A study of Bombyx mori with 9 samples.

How the data were processed

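Silk glands of Bombyx mori strains A306, A798 and XH were taken on day 5 of the fifth larval instar, with 3 libraries per strain made from total RNA extracted with TRIzol, per the labels' protocols. The submitters' processing notes name fastp 0.19.5, StringTie 1.3.3b and DESeq2 1.24.0; the aligner, the genome build and the annotation are not given in the sources used here. The authors deposited a table of FPKM values, given to 2 decimals, for 15745 features: 14623 genes with BGIBMGA identifiers and 1122 ENSRNA models of ribosomal, transfer and other small RNAs. A second deposited table, although named for raw counts, holds FPKM of 5 genes that equal those of the first (largest difference 0), together with their annotation. No count table was analysed here, so no count test was run. The 3 columns of strain means in each table were not used.

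FPKM divide by gene length and by the mapped total, so a feature that takes a large share of a library lowers the values of all others, and the total gives no depth. Low values were searched for the steps that single fragments leave. Of 342 features above 0 in 3 to 6 libraries with values of 0.3 to 3 FPKM, 12 had values close enough to each other to be such steps, too few to estimate relative depth, which is therefore unknown. Exact zeros need care: 5418 features were listed at 0 in all libraries, among them 6 ribosomal protein genes, which every cell uses. A 0 can thus be a failed estimate, and for strains at 0 the value of each library is given with no fold change. Paralogs such as the 30K lipoproteins, cuticle proteins and gloverins share sequence, and how the authors' counting split reads between them is not known.

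Gene names and descriptions were taken from the deposited table. None of its identifiers (0) matched the RefSeq gene table at hand, and no genome was given, so genome positions are not reported. Of 14623 BGIBMGA genes 1099 carried a description, as did 579 of the 4636 features tested, so most changed genes could not be assigned to a list.

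Features with FPKM of at least 1 in at least 3 of the 9 libraries were kept (4636, 24 of them ENSRNA models). Values were put on the log2 scale as log2(FPKM + 1), on which changes of low genes are understated. The limma package (3.58.1, R 4.3.3) fitted strain means to all 9 libraries at once, with empirical Bayes variances that follow an intensity trend, and Benjamini-Hochberg adjustment over the features of a comparison; calls have an adjusted p below 0.05, two-sided, with no fold minimum. Comparisons were A306 against A798 and XH against A798, which the submitters name, A306 against XH, which 3 groups imply, and the overlap of the first 2. Gland weights were compared by an exact permutation test of the mean of the 2 weights per sample.

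There were 32 gene lists, fixed as topics before the data were examined and matched by symbols and words of the description after the files could be read. Lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01 between genes, and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists and comparisons. The lists for insulin and TOR signalling, amino acid and sugar transporters and transposable elements had no tested gene (0), those for ribosome biogenesis and midgut had 1, and those for apoptosis, juvenile hormone and muscle had 2; none of these 8 lists was tested. Matching by words put some genes in a list they do not belong to: FMBP-1 stands among silk structural proteins, SERPIN-9 is the single midgut match, and vacuolar ATPase subunits stand in oxidative phosphorylation. No sericin gene was matched.

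Genes were named by a rule set before the data were examined. Per comparison these were all measured members of the silk structural list. To them were added the 8 highest and 8 lowest changes among called genes with a name, a mean FPKM of at least 5 in the higher strain and the 3 libraries of one strain beyond those of the other. From each list described, up to 4 called members with the largest change were taken, or the member with the highest FPKM where none was called. For genes changed the same way in both strains against A798, the 5 highest and 5 lowest by the smaller of the 2 changes were taken. The genes of the second table were named because the authors deposited them apart, for a reason not stated.

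The procedure was tested on simulated data with the means and residual spread of the 4636 features and 200 changed genes in 10 simulations per comparison. For A306 against A798, 29.0% of genes changed 1.5-fold, 48.4% of those changed 2-fold and 72.0% of those changed 4-fold were recovered, and 6.05% of calls were false. For XH against A798 the shares were 26.3%, 51.0% and 72.3%, with 5.78% false, and for A306 against XH 33.3%, 52.1% and 75.3%, with 6.23% false. A list of 10 genes shifted by 0.5 on the log2 scale was called by camera in 10 of 10 simulations of each comparison. Among unshifted lists, 3 calls were made for A306 against A798, 1 for XH against A798 and 1 for A306 against XH. Genes were drawn independently, so this does not show how camera fares on lists whose genes vary together. In the data between 1563 and 2204 features were called per comparison, far more than the 200 changed here. No factor common to the genes of a library was simulated. The recovered and false shares therefore need not hold for the data.

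Alternatives were pseudocounts of 0.1 and 0.5, no filter, FPKM of at least 5 in at least 3 libraries, TMM scaling, median centring, equal FPKM sums outside the 20 most abundant genes, quantile normalization, fits to the 6 libraries compared, a replicate block, leaving out each library, robust variances, no intensity trend, a 2-fold minimum and an adjusted p below 0.01. Chosen after seeing the data were the removal of ENSRNA features with scaling on the remaining sum, and the removal of genes listed at 0 in all 3 libraries of a strain. Figures were drawn with matplotlib 3.10.9.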

Results

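RNA was sequenced from silk glands of 3 pure strains of the domestic silkworm, Bombyx mori. The silk gland is the larval organ that makes the silk proteins, which leave the animal as the cocoon thread. The strains, named A306, A798 and XH, were raised under the same conditions and sampled on the fifth day of their last larval instar, before spinning. There were 3 libraries per strain, 9 in all. Expression was given as FPKM, fragment counts divided by transcript length and by the mapped total of the library, for 15745 features, so the depth of each library is unknown. The FPKM of a library summed to between 502510 in A798 replicate 2 and 587872 in A306 replicate 1. The 20 most abundant features took 35.0% of the sum in XH replicate 3 and 46.1% in A798 replicate 3. Ribosomal RNA models took 5.05% and 19.6% of the sum in the same libraries, and between 6.23% and 11.3% in the other 7. Over the 4636 features tested, log2 values of libraries of one strain correlated across genes at r = 0.961 to 0.966, and those of different strains at r = 0.872 to 0.916. Nothing in the labels says whether the 3 libraries of a strain came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

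The strains were chosen by the submitters for their silk gland weight, to look for genes tied to gland development. Each sample carries 2 stated gland weights, and the labels do not say whether these are from 2 animals, 2 sexes or 2 glands. Their mean per sample was 0.688 ± 0.0207 g in A306, 0.974 ± 0.00850 g in XH and 1.28 ± 0.0309 g in A798 (mean ± SD, n = 3 samples each). A306 glands thus weighed 53.7% of A798 glands, and XH glands 76.0%. All 3 samples of a lighter strain lay below all 3 of a heavier one in each pair of strains. The exact two-sided permutation test gave p = 0.1 for each of the 3 pairs, the smallest p that 3 samples against 3 allow.

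**Figure D1:**
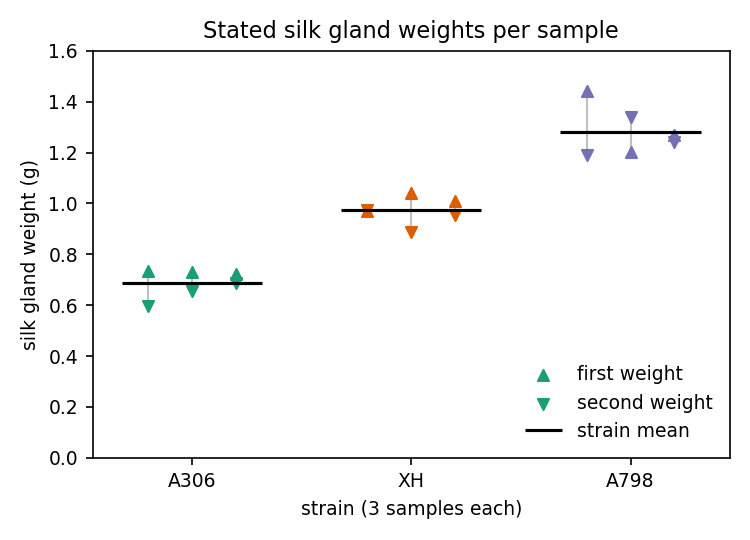
Silk gland weight in grams (vertical axis) for the 3 samples of each strain (horizontal axis); triangles are the first and second weight stated for a sample, and the line is the strain mean. The strain means are 0.688 g in A306, 0.974 g in XH and 1.28 g in A798.

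The first comparison set A306, the strain with the lightest glands, against A798, the heaviest. FPKM of the genes of the fibroin complex did not move together. The fibroin heavy chain gene (BGIBMGA005111), which encodes the main protein of the silk filament, was 3.19-fold lower in A306, at 268 ± 5.81 against 854 ± 34.1 FPKM (mean ± SD, n = 3; log2 change -1.67 ± 0.0375 SE, limma adjusted p = 2.95e-08). The fibroin light chain gene (FIBL), whose product is bonded to the heavy chain, stood at 23739 ± 171 FPKM in A306 and 20106 ± 600 in A798. P25 (fibrohexamerin), the third partner of the complex, stood at 4617 ± 61.2 and 3862 ± 156 FPKM. The fitted log2 changes of these 2 genes, 0.24 and 0.26, passed the threshold (adjusted p = 0.000269 and 0.000343), but they lay 0.07 and 0.05 below the median change of all genes tested, 0.31, and turned negative under TMM scaling and median centring. FIBL was called lower in A306 under both (adjusted p = 0.00264 and 0.0127, over all alternatives from 0.000194 to 0.199), and P25 under TMM scaling (adjusted p = 0.0349, over all alternatives from 0.000123 to 0.234). The heavy chain remained lower in A306 under every scaling tried. FPKM of the heavy chain as a percentage of that of the light chain, a measure that a single factor per library leaves unchanged, was 1.13 ± 0.0322 in A306 and 4.25 ± 0.271 in A798 (n = 3). Light chain FPKM per P25 FPKM was 5.14 ± 0.103 and 5.21 ± 0.0918. A heavy chain gene model that matched the strains' sequences unequally would change its FPKM and its percentage of the light chain alike. This was not tested, nor was how much of the heavy chain transcript the gene model covers. Both limits hold for every pair of strains.

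Transcripts of the storage proteins and 30K lipoproteins, which the fat body makes for the haemolymph, were far lower in A306 than in A798. Of 13 measured genes of the list of fat body and haemolymph proteins, 11 fell, none rose, and 2 did not pass the test; adjusted over the list alone the count was also 11. The list's median log2 change was -2.68, or -2.98 relative to the median of all genes (camera adjusted p = 1.36e-15, and adjusted p = 0.0301 with an estimated correlation). Over all alternatives the median ran from -3.01 to -0.60, the latter without a filter on low values. SP1, a storage protein that accumulates mainly in female larvae, was at 0.0467 ± 0.0404 FPKM in A306 and 60.2 ± 4.31 in A798; the labels do not give the sex of the animals. The lipoprotein genes BMO.4927 (21G1), BMO.682 and LP (PBMHP-6) were at 1.27 ± 0.183, 17.5 ± 0.665 and 11.1 ± 1.78 FPKM in A306. In A798 the same 3 genes were at 56.3 ± 3.10, 174 ± 4.16 and 111 ± 4.59 FPKM (n = 3; log2 changes -4.66, -3.24 and -3.21). All 7 measured immune effector genes fell as well, 7 also adjusted over the list alone (camera adjusted p = 2.44e-07, and adjusted p = 0.0301 with an estimated correlation). Their median log2 change of -2.12 is that of BGLOV2, which was listed at 0 in A306, so the pseudocount sets it. The median ran from -4.60 to -1.59 over the 23 alternatives in which the list had enough members to test. Without genes listed at 0 in a whole strain it was -2.46. The lysozyme gene BGIBMGA010439 had a log2 change of -3.20, from 18.1 ± 5.36 FPKM in A798. The antibacterial peptide genes GLV3 and BGLOV2 were listed at 0 in all 3 A306 libraries, and in A798 at 3.89, 4.77 and 3.59 FPKM and at 2.04, 4.16 and 4.23 FPKM. Lebocin (LEB1/2) was at 0.0633 ± 0.110 FPKM in A306 and 4.83 ± 0.194 in A798.

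Of the lists for protein synthesis, entry into the endoplasmic reticulum and protein breakdown, the proteasome list alone passed the camera test in A306 against A798 as deposited, while under TMM scaling and median centring it was lost and the ribosomal protein list passed as lower. All 4 measured aminoacyl-tRNA synthetase genes rose, among them those for glycine (BGIBMGA007637, log2 change 0.89) and alanine (BGIBMGA006216, 0.85), the most common residues of fibroin; the list test gave an adjusted p of 0.0718, and the phenylalanine enzyme subunit FRSB (0.27) turned negative under TMM scaling, median centring and quantile normalization. Of 10 measured proteasome genes 9 rose, 9 also adjusted over the list alone, with a median log2 change of 0.59, or 0.29 relative to all genes. The list's adjusted p of 0.0216 by camera became an adjusted p of 0.427 with an estimated correlation, and the call was also lost under all 4 planned scalings, with FPKM of at least 5 in 3 libraries and without the ENSRNA features. Calreticulin (CRT), a chaperone of the endoplasmic reticulum, was 889 ± 40.3 against 163 ± 66.3 FPKM. The translocon subunit SEC61ALPHA was 2231 ± 42.8 against 1415 ± 40.3 FPKM. Of 43 measured ribosomal protein genes 26 rose and 3 fell, but their median change of 0.17 lay 0.14 below that of all genes and became -0.21 under TMM scaling and -0.16 under median centring. The list passed as lower in A306 under these scalings (adjusted p = 0.00014 and 0.00933, over all alternatives from 0.00014 to 0.91), and as higher without a filter on low values. Of 16 measured genes of oxidative phosphorylation 9 rose and 1 fell; the one that fell encodes a subunit of the vacuolar ATPase, a proton pump outside the respiratory chain (BGIBMGA013678). The 3 measured genes of the ecdysone list rose (camera adjusted p = 0.0168, and adjusted p = 0.255 with an estimated correlation; the call was also lost with FPKM of at least 5 in 3 libraries). They were ecdysone oxidase (BGIBMGA000158, 5542 ± 91.3 against 2216 ± 77.5 FPKM), an ecdysteroid-regulated protein (BGIBMGA008405, 373 ± 6.79 against 174 ± 15.8 FPKM) and USP, a partner of the ecdysone receptor. USP was listed at 0 in all A798 libraries and at 14.5, 12.7 and 9.70 FPKM in A306. The pseudocount thus sets the size of its change. Without genes listed at 0 in a whole strain, the ecdysone list kept too few members to test.

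Among single genes with a name and with all 3 libraries of one strain beyond the 3 of the other, the highest changes in A306 were those of the lipase BGIBMGA012648, RABB, USP, the Kazal-type proteinase inhibitor BGIBMGA011573, the cuticle protein BMORCPH21, HTRA2, CRT and RAB11. The lipase, RABB and HTRA2 were listed at 0 in all A798 libraries. Their A306 libraries were at 19.1, 27.6 and 29.2 FPKM, at 20.2, 17.4 and 12.6 FPKM, and at 7.51, 4.27 and 6.40 FPKM. BGIBMGA011573 was at 25.6 ± 4.74 against 2.25 ± 1.04 FPKM, BMORCPH21 at 11.4 ± 1.83 against 0.947 ± 0.966, and the vesicle transport GTPase RAB11 at 98.2 ± 12.7 against 17.6 ± 5.40. The lowest changes were those of SP1, BMO.4927, the cuticle protein BMORCPR101, a reticulon-like gene, a cytochrome b5 gene, a glutathione S-transferase gene, BMO.682 and LP. BMORCPR101 was at 0.127 ± 0.125 against 24.1 ± 1.80 FPKM. The reticulon-like gene BGIBMGA005861 was listed at 0, 9.79 and 0 FPKM in the A306 libraries and at 46.5 ± 6.38 in A798. The cytochrome b5 gene BGIBMGA014207 was at 4.13 ± 4.78 against 65.1 ± 13.0 FPKM. The glutathione S-transferase BGIBMGA009107 was listed at 0 in all A306 libraries and at 11.5, 15.9 and 9.07 FPKM in A798. Of 7 measured heat shock genes 5 rose and 2 fell in A306 as deposited. The small heat shock protein genes BGIBMGA005781 (0.907 ± 0.166 against 12.4 ± 0.967 FPKM) and HSP20.4 (60.1 ± 4.95 against 149 ± 9.23) were lower, other small heat shock protein genes were among those that rose, and HSP90 was 2.07-fold higher (526 ± 16.8 against 254 ± 6.16 FPKM).

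In total 1759 features were higher and 445 lower in A306 than in A798 at an adjusted p below 0.05 (limma on log2(FPKM + 1), all 9 libraries in one fit), of which 425 and 241 changed at least 2-fold. The 3 libraries of one strain all lay beyond the 3 of the other for 56.7% of features. By chance 10% would, where no factor is common to the genes of a library. The median log2 values of the libraries were 2.74 to 2.78 in A306, 2.66 to 2.69 in XH and 2.40 to 2.46 in A798. They did not overlap in any pair of strains, and such a factor would raise the share of features without overlap. The higher calls made up 79.8% of the total as deposited. This share was 48.8% under TMM scaling, 47.6% under median centring, 67.3% with the FPKM sum outside the 20 most abundant genes made equal, 53.5% under quantile normalization, and 67.5% without the ENSRNA features.

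**Figure D2:**
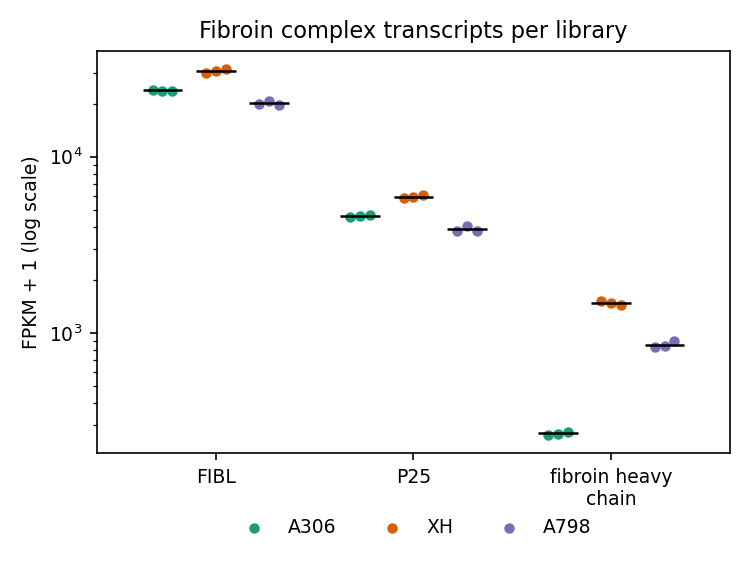
Expression in FPKM plus 1 (vertical axis, log scale) of the fibroin light chain (FIBL), P25 and the fibroin heavy chain; each point is 1 library, colours are strains, and lines are strain means. The heavy chain averages 268 FPKM in A306, 1479 in XH and 854 in A798, while FIBL averages 23739, 30547 and 20106.

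The second comparison set XH, with glands of intermediate weight, against A798. All fibroin complex genes were higher in XH. The fibroin heavy chain was 1.73-fold higher (1479 ± 40.5 against 854 ± 34.1 FPKM, n = 3; log2 change 0.79 ± 0.0375 SE, adjusted p = 3.32e-06). FIBL was at 30547 ± 819 against 20106 ± 600 FPKM (log2 change 0.60, adjusted p = 3.07e-06) and P25 at 5912 ± 102 against 3862 ± 156 FPKM (0.61, adjusted p = 4.85e-06). The fourth gene on the list of silk structural proteins, FMBP-1, binds the fibroin gene and is no part of silk; it was at 11.0 ± 1.24 and 9.97 ± 1.85 FPKM (adjusted p = 0.602). The list as a whole had an adjusted p of 0.0646 by camera, and passed under median centring and without a filter on low values. Heavy chain FPKM as a percentage of light chain FPKM was 4.85 ± 0.262 in XH and 4.25 ± 0.271 in A798. The transcription factor SGF1 was at 48.5 ± 0.550 and 51.4 ± 2.25 FPKM (adjusted p = 0.409), and SGF3 at 37.1 ± 1.88 and 44.8 ± 1.69 (adjusted p = 0.0238). The SGF3 call was lost when A798 replicate 1 or 2 or XH replicate 1 or 2 was left out, with adjusted p from 0.0503 to 0.0758.

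The fat body and haemolymph genes, which were low in A306, were higher in XH than in A798. All 13 rose, 13 also adjusted over the list alone, with a median log2 change of 1.21 (camera adjusted p = 2.2e-07, and adjusted p = 0.0973 with an estimated correlation). SP2 was at 154 ± 1.82 against 30.9 ± 1.75 FPKM, SP3 at 186 ± 2.12 against 38.5 ± 2.44, the 30K protein gene BGIBMGA004398 at 16.2 ± 1.90 against 2.99 ± 0.413, and LP at 394 ± 19.1 against 111 ± 4.59. Markers of other tissues also moved in XH. The 3 measured haemocyte genes rose, the phenoloxidase gene PRO-PO2 from 0.700 ± 0.0964 to 3.63 ± 0.299 FPKM, with an adjusted p of 0.0934 for the list, which passed under TMM scaling, median centring and quantile normalization and without a filter on low values. Both measured muscle genes rose: the myosin light chain gene MLC-2 was at 3.41 ± 0.777 against 0.243 ± 0.235 FPKM, and muscle-type actin A1 at 62.0 ± 2.65 against 38.2 ± 2.95. Unlike the fat body genes, A1 was also higher in A306 than in A798, at 72.9 ± 3.74 FPKM (log2 change 0.91, adjusted p = 2.44e-05). Of 26 measured cuticle genes 16 rose and 1 fell, with a median log2 change of 0.87. The list's camera adjusted p was 0.0646, and it passed under all 4 planned scalings. Without a filter on low values the median was 0.08, with a camera adjusted p of 0.514. Without genes listed at 0 in a whole strain it was 0.85, with a camera adjusted p of 0.0734. Both measured juvenile hormone binding protein genes rose, AN0895 from 6.59 ± 1.10 to 35.3 ± 1.23 FPKM and HJHBP from 0.463 ± 0.253 to 2.74 ± 1.04 FPKM. In A306 AN0895 was higher than in A798 too, at 15.2 ± 2.08 FPKM (adjusted p = 3e-04), and HJHBP did not pass the test, at 0.113 ± 0.115 FPKM (adjusted p = 0.231). Immune effectors went the other way: 3 of 7 fell, 3 also adjusted over the list alone, and the other 4 did not pass the test (median log2 change -0.80, camera adjusted p = 0.00515, and adjusted p = 0.12 with an estimated correlation). BGLOV2, LEB1/2 and GLV3 were the ones that fell, by 1.17, 1.11 and 1.08 on the log2 scale. Without genes listed at 0 in a whole strain the immune median was -0.05, with an adjusted p of 0.386.

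All 4 aminoacyl-tRNA synthetase genes were higher in XH too, 4 also adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.255 with an estimated correlation; the call was also lost with FPKM of at least 5 in 3 libraries). The glycine enzyme gene BGIBMGA007637 was at 132 ± 1.84 against 68.4 ± 1.54 FPKM and the alanine enzyme gene BGIBMGA006216 at 75.2 ± 0.211 against 42.2 ± 1.02. Of 43 ribosomal protein genes 26 rose and 2 fell, at a median change of 0.19, which lay 0.01 below that of all genes. Among them RPS2 rose from 5776 ± 122 to 9744 ± 138 FPKM. Proteasome genes were mixed, with 3 of 10 higher and 1 lower. Of 7 heat shock genes 3 rose, 1 fell and 3 did not pass the test: HSP90 (log2 change 0.66), HSP70-14 (0.56) and BGIBMGA005781 (0.85) rose, and HSP20.4 fell (-0.24, adjusted p = 0.0306). The HSP20.4 call was lost when A798 replicate 1 or 2 or XH replicate 2 or 3 was left out, with adjusted p from 0.0596 to 0.0928.

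The highest named changes in XH were those of the mitochondrial ATP synthase gamma subunit gene BGIBMGA013965, the lipases BGIBMGA012648 and BGIBMGA014574, the protease inhibitor SERPIN-9, the cuticle proteins BMORCPG17, BMORCPH21 and BMORCPG16, and the sulfiredoxin gene BGIBMGA007947. BGIBMGA013965 was listed at 0 in all A798 and A306 libraries and at 146, 133 and 134 FPKM in XH. BGIBMGA012648 was listed at 0 in A798 and at 85.1, 90.7 and 96.5 FPKM in XH. SERPIN-9 was at 38.7 ± 0.991 against 0.637 ± 0.280 FPKM, and BGIBMGA014574 at 42.3 ± 1.03 against 7.59 ± 0.138. The 3 cuticle genes were at 20.2 ± 8.15, 22.6 ± 4.08 and 8.91 ± 1.71 FPKM in XH and at 0.583 ± 1.01, 0.947 ± 0.966 and 0.410 ± 0.401 in A798. Sulfiredoxin was at 21.5 ± 10.9 against 3.35 ± 2.52 FPKM, with an adjusted p of 0.0465 that rose to between 0.0535 and 0.136 without any one of A306 replicate 1 or 3, A798 replicate 1, 2 or 3, and XH replicate 1 or 3. The lowest changes were those of BMORCPR101 (0.0800 ± 0.139 against 24.1 ± 1.80 FPKM), a phosphate co-transporter, the carboxylesterase AE13 (0.403 ± 0.186 against 14.6 ± 0.705), the beta-galactosidase GAL, alkaline phosphatase BGIBMGA009866, BGIBMGA010102, BMSUC1 and BMDJ-1BETA. The phosphate co-transporter gene BGIBMGA014105 was listed at 0 in all XH libraries and at 12.5, 23.5 and 8.21 FPKM in A798. The log2 changes of the last 4 ran from -1.26 in BGIBMGA009866 to -0.91 in BMDJ-1BETA.

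In total 1191 features were higher and 372 lower in XH than in A798, 283 and 156 of them by at least 2-fold. All 3 libraries of one strain lay beyond those of the other for 46.3% of features. By chance 10% would, where no factor is common to the genes of a library. The median log2 change of all features was 0.19. Higher calls made up 76.2% as deposited, 50.7% under TMM scaling, 44.1% under median centring, 67.2% with the FPKM sum outside the 20 most abundant genes made equal, 52.2% under quantile normalization and 69.4% without the ENSRNA features.

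**Figure D3:**
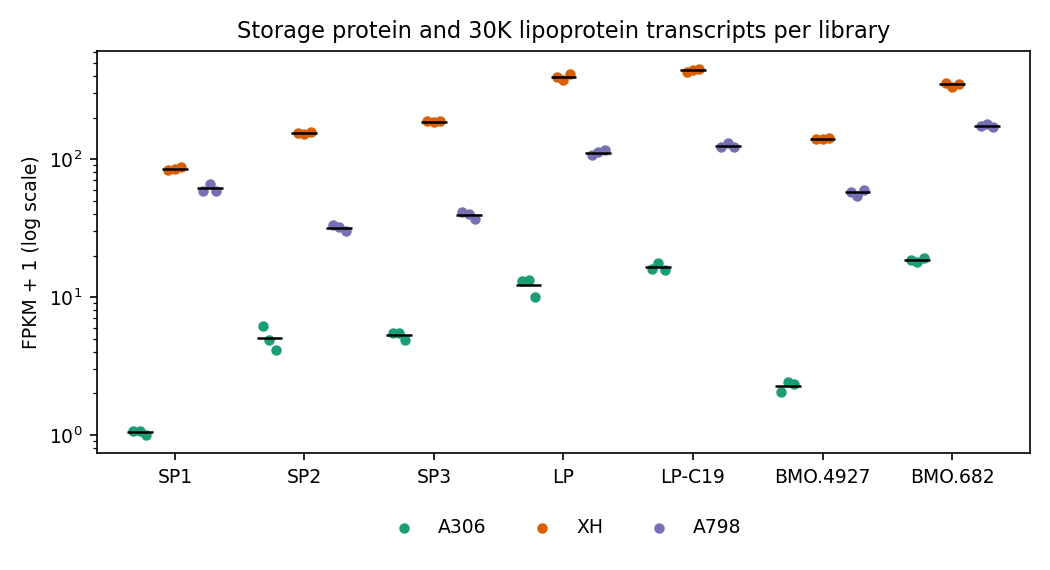
Expression in FPKM plus 1 (vertical axis, log scale) of 3 storage protein genes and 4 genes of 30K lipoproteins; each point is 1 library, colours are strains, and lines are strain means. For each gene shown the A306 libraries lie lowest and the XH libraries highest; SP1 averages 0.0467 FPKM in A306, 60.2 in A798 and 83.8 in XH.

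Both strains with lighter glands were then set against A798 together. The named genes higher in both included the lipase BGIBMGA012648, the cuticle proteins BMORCPH21 and CPG43, the Kazal-type inhibitor BGIBMGA011573 and the gene BGIBMGA001107, described as a DNA supercoiling factor. BGIBMGA001107 was at 171 ± 8.82 FPKM in A306, 191 ± 0.764 in XH and 52.6 ± 1.46 in A798 (n = 3 each). CPG43 was at 81.8 ± 45.4, 85.2 ± 25.6 and 24.7 ± 10.2 FPKM, and its call in A306 was lost under TMM scaling, median centring and quantile normalization. The named genes lower in both included BMORCPR101, BMSUC1, GAL, RPA43_N and TEF2. BMSUC1 encodes beta-fructofuranosidase, an enzyme that splits sucrose; it was at 1170 ± 9.10 FPKM in A306, 1725 ± 14.3 in XH and 3417 ± 57.8 in A798. TEF2, translation elongation factor 2, was at 380 ± 59.0, 845 ± 87.7 and 1353 ± 181 FPKM. GAL was at 5.38 ± 0.733, 3.95 ± 0.803 and 11.2 ± 1.38 FPKM, and RPA43_N, described as a protein with an RNA polymerase I subunit domain, at 7.09 ± 0.645, 7.96 ± 1.37 and 15.6 ± 2.03. In all, 784 features were higher and 142 lower in both strains as deposited. The counts were 303 and 321 under TMM scaling, 271 and 335 under median centring, and 318 and 271 under quantile normalization. Independent lists of the same sizes would share 452 and 35.7 features. In 100 simulations all 9 libraries were drawn anew with no gene changed, and both comparisons used the same drawn A798 libraries. Shared calls averaged 0.02 higher and 0.01 lower. With no gene changed almost no gene is called in either comparison, so these counts are no baseline for the shared calls. Across genes, which are not independent replicates, the 2 sets of log2 changes correlated at r = 0.30, against 0.50 in the simulations, where the shared libraries are the only link. Their covariance was 0.236, against 0.0688 in the simulations, a difference of 0.167. This difference is net of the sharing of libraries as simulated, with genes drawn independently. With 3 A798 libraries the controls could not be split to check it. In the simulations the changes spread by noise alone, so the 2 values of r are not on a like scale. The overlap counts of 784 and 142 are not corrected for the sharing. A further 198 features passed the test in opposite directions, 111 lower in A306 and higher in XH and 87 the other way, and all 198 also differed between A306 and XH.

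The third pair, A306 against XH, was not named as a comparison by the submitters. The fibroin genes were lower in A306: the heavy chain by 5.53-fold (268 ± 5.81 against 1479 ± 40.5 FPKM, log2 change -2.46 ± 0.0375 SE, adjusted p = 1.63e-09), FIBL and P25 by 0.36 each on the log2 scale, with FMBP-1 at 10.8 ± 2.12 and 11.0 ± 1.24 FPKM. For the list of silk structural proteins the camera adjusted p was 0.0145, and adjusted p = 0.174 with an estimated correlation; the call was also lost under quantile normalization (adjusted p over all alternatives from 0.000861 to 0.174). All 13 fat body and haemolymph genes were lower in A306, 13 also adjusted over the list alone, with a median log2 change of -4.23 (camera adjusted p = 1.84e-16, and adjusted p = 0.0301 with an estimated correlation) that was -1.49 without a filter on low values. SP1, BMO.4927, SP3, LP, SP2 and LP-C19 were among the 8 lowest changes, at log2 changes from -6.34 to -4.75. The other 2 were BGIBMGA013965, listed at 0 in A306, and the lipase BGIBMGA014574 (0.527 ± 0.181 against 42.3 ± 1.03 FPKM). Of 7 immune genes 6 were lower in A306, led by lysozyme BGIBMGA010439 (log2 change -3.56, against 22.8 ± 2.41 FPKM in XH; list adjusted p = 0.000648, and adjusted p = 0.0973 with an estimated correlation). Of 26 cuticle genes 11 were lower and 3 higher, 12 and 3 adjusted over the list alone (list adjusted p = 0.00515, and adjusted p = 0.0973 with an estimated correlation). BMORCPG17 and BMORCPR32 were listed at 0 in all A306 libraries, and in XH at 26.1, 23.6 and 10.9 FPKM and at 5.08, 3.92 and 5.76 FPKM. Against that trend the cuticle protein gene BGIBMGA005303 (CPH44) was at 12461 ± 721 FPKM in A306 and 3681 ± 241 in XH. Of 3 haemocyte genes 2 were lower, PRO-PO2 by 2.11 on the log2 scale; the list's adjusted p of 0.0428 became an adjusted p of 0.255 with an estimated correlation, and the call was lost in 14 of 23 alternatives, among them both other pseudocounts, all 4 planned scalings, the replicate block and the removal of ENSRNA features. The adjusted p lay between 0.0534 and 0.0758 without any one of A306 replicate 1 or 2, A798 replicate 2, and XH replicate 1 or 2.

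All 10 proteasome genes were higher in A306 than in XH, 10 also adjusted over the list alone, at a median log2 change of 0.37, or 0.25 relative to all genes (camera adjusted p = 0.00515, and adjusted p = 0.296 with an estimated correlation). The call was also lost under quantile normalization, and the adjusted p over all alternatives ran from 6e-06 to 0.296. The largest changes among them were 0.61 in BMO.3609 and 0.57 in BMO.323. The 8 highest named changes in A306 were those of BGIBMGA014105, RABB, USP and HTRA2, listed at 0 in all XH libraries, and of AE13, CRT, BGIBMGA011573 and BGIBMGA005303. AE13 was at 14.4 ± 0.573 against 0.403 ± 0.186 FPKM and CRT at 889 ± 40.3 against 112 ± 19.7. In total 1071 features were higher and 622 lower in A306 than in XH, 324 and 353 by at least 2-fold. Libraries did not overlap for 50.1% of features, against 10% by chance where no factor is common to the genes of a library. The median log2 change was 0.12. Higher calls made up 63.3% as deposited, 48.1% under TMM scaling, 54.0% under median centring, 53.0% with the FPKM sum outside the 20 most abundant genes made equal, 52.4% under quantile normalization and 51.5% without the ENSRNA features.

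**Figure D4:**
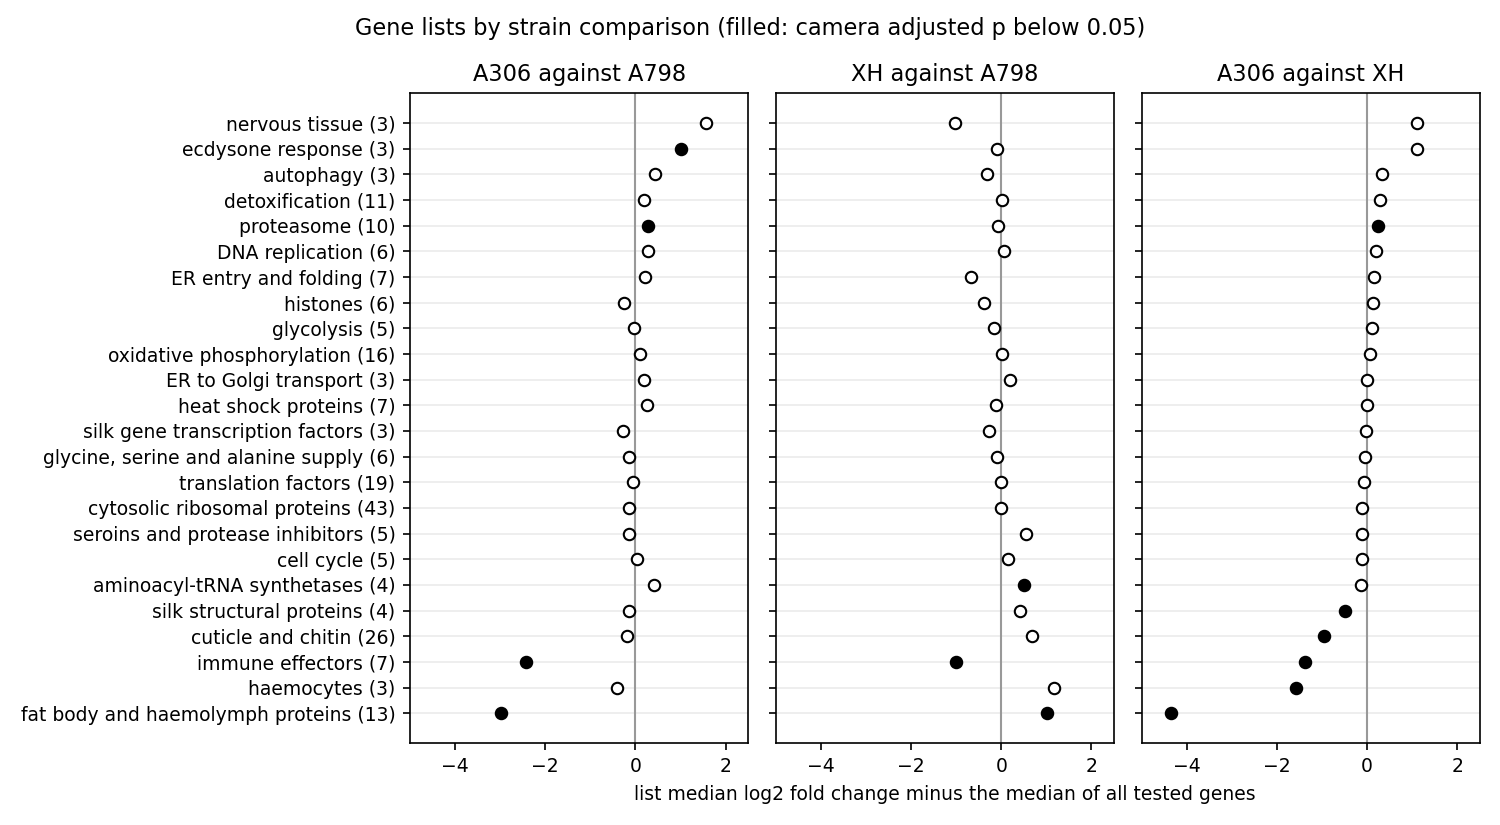
Median log2 fold change of each gene list minus the median of all tested genes (horizontal axis) for the 3 strain comparisons (panels); the number of measured genes is in parentheses, and filled circles passed the camera test. The fat body and haemolymph list lies at -2.98, 1.01 and -4.35, and lists without a filled circle did not pass in that panel.

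Of 72 tests of 24 lists in 3 comparisons, 13 passed, and 3 passed with an estimated correlation: the fat body list in A306 against A798 and against XH, and the immune list in A306 against A798. In the 13 the median, mean and test had the same sign. Among the other 59 the median and mean differed in sign in 11 and the median and test in 18. For the silk structural list in A306 against A798, for example, the median was 0.17 and the mean -0.27, with a camera adjusted p of 0.65. Lists that passed in none of the comparisons are given by their median log2 change in A306 and in XH, each against A798. These were 0.17 and 0.74 for seroins and protease inhibitors, 0.03 and -0.08 for silk gene transcription factors, 0.26 and 0.18 for translation factors, and 0.51 and -0.47 for entry into the endoplasmic reticulum and folding, a list in which 3 of 7 members are RNAs of the signal recognition particle. They were 0.51 and 0.38 for transport from the endoplasmic reticulum to the Golgi, 0.75 and -0.12 for autophagy, 0.59 and 0.25 for DNA replication, 0.35 and 0.35 for the cell cycle, and 0.17 and 0.10 for glycine, serine and alanine supply. They were 0.27 and 0.03 for glycolysis, 0.40 and 0.20 for oxidative phosphorylation, 0.56 and 0.07 for heat shock proteins, 0.49 and 0.21 for detoxification, 0.06 and -0.18 for histones, and 1.86 and -0.84 for nervous tissue, whose 3 members are all neuropeptide-like genes. Among lists too short to test, the median was 0.39 and -0.10 for the 2 measured apoptosis genes, and the 1 measured gene of ribosome biogenesis changed by 1.47 and 1.21.

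The submitters also deposited a separate annotated table of 5 genes, with the same FPKM values as the main table. Why these genes were deposited apart is not stated. Their values come from the same samples, so they are no independent evidence of any direction. BMSUC1 is one of them. The glucose dehydrogenase gene BGIBMGA005711 was at 0.610 ± 0.0700 FPKM in A306, 2.63 ± 0.260 in XH and 212 ± 14.2 in A798 (n = 3 each). The alkylglycerol monooxygenase gene BGIBMGA002524 was at 0.243 ± 0.166, 7.03 ± 1.48 and 17.9 ± 0.482 FPKM, and the odorant binding protein gene BGIBMGA002629 at 433 ± 18.4, 322 ± 24.2 and 680 ± 16.3. These genes were lower in both A306 and XH than in A798 (adjusted p between 8.91e-10 and 0.000517). The gene BGIBMGA010889, described as zonadhesin, was at 8.72 ± 0.903 FPKM in A306, 132 ± 5.49 in XH and 12.7 ± 2.21 in A798. It was lower in A306 than in A798 (adjusted p = 0.0125) and higher in XH (adjusted p = 7.17e-07).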

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

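The tests of tissue mixing, of other tissues, of scaling, of abundant features, of the detection floor, of a common factor and of gene models were chosen only after the result was seen, while the splits of the libraries and the test of zeros in single libraries were chosen before.

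Results in which A306 and XH differed in their change against A798 are given here. The A798 libraries cancel in that difference, so it equals A306 minus XH and was tested as such. The fibroin heavy chain differed by -2.46 on the log2 scale (limma adjusted p = 1.63e-09), being lower than A798 in 3 of 3 A306 libraries and higher in 3 of 3 XH libraries. The gene lists that differed were fat body and haemolymph proteins (median -4.23), haemocytes (-1.46), immune effectors (-1.25), cuticle and chitin (-0.83), silk structural proteins (-0.36) and proteasome (0.37). The immune median is that of ATTACIN1, listed at 0 in A306, so the pseudocount sets it. These lists could be tested in 24 alternatives, or 23 for haemocytes and immune effectors. Over these the medians ran from -4.96 to -1.49 for fat body, -2.24 to -0.39 for haemocytes and -3.63 to -1.09 for immune effectors. They ran from -1.03 to -0.0672 for cuticle, -0.51 to -0.34 for silk and 0.18 to 0.41 for proteasome. Of these, the fat body list passed with an estimated correlation between genes (adjusted p = 0.0301), and the other 5 did not (adjusted p from 0.0973 to 0.296). In all, 198 genes were called in opposite directions against A798.

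Fat body and haemolymph transcripts were lower in A306 and higher in XH than in A798. One tissue mix carried over in different amounts would give every member the same ratio of XH to A798 above the A306 level, but over 11 members the ratio ran from 1.39 in SP1 (2-SE interval 1.27 to 1.52) to 6.46 in BGIBMGA004398 (4.96 to 8.42), which is 4.65 times higher; SP1 is a sex-specific storage protein and the labels do not give the sex, and the next lowest ratio was 2.11 in BMO.682 (2.00 to 2.22). Scaling of the libraries is argued against by a list median of at least 0.966 in size under 5 scalings in both comparisons. More tissue of every other kind in the XH samples stays open. Of 4 other marker lists 3 had a median above that of all genes, haemocytes by 1.17, muscle by 1.06 from 2 genes and cuticle by 0.68. Without a filter on low values the cuticle median was 0.08 (camera adjusted p = 0.514), against 0.04 for all genes. The 3 nervous tissue genes went both ways (median -0.84, mean 0.28, camera adjusted p = 0.559). More such tissue in XH would not raise these markers in A306. Of 2 muscle genes, actin A1 (0.91) was higher in A306 than in A798 and MLC-2 was not called. Of 3 haemocyte genes, PPO1 (0.53, lost under all 4 planned scalings) was higher and 1 was not called. PRO-PO2 was lower, at 0.03, 0.16 and 0.03 FPKM in A306 against 0.63, 0.66 and 0.81 in A798. A strain difference in the fat body and haemolymph transcripts, in the gland or in tissue carried over with it, was not tested and also stays open. Unequal ratios do not bear on it. A difference in which tissues and animals entered the samples was not tested either and stays open.

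More genes were higher than lower in A306 and in XH against A798. With libraries scaled on the genes outside the 20 most abundant, the lower of both shares of higher calls was 67.2%, so a few abundant features were not the whole cause. With FPKM of at least 5 in 3 libraries it was 77.1%, which argues against genes near the detection floor. One factor common to most genes of a library stays open, since TMM scaling gave 48.8% but its centring fixes that outcome. Without counts or spiked standards a strain difference in most genes cannot be told apart from such a factor.

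Some genes were listed at 0 in every library of 1 strain and expressed in another, with FPKM of at least 5 in all of its libraries: 32 at 0 in A306, 26 in A798 and 32 in XH. Failed estimates in single libraries would fall without regard to strain. Zeros filled whole strains in 14.03% of 549 genes with a 0 and FPKM of at least 5 in some library. Over 100 other groupings, none of which kept a strain whole, the share was at most 1.09%. In the rest of the 549 genes some strain had both zeros and values above 0. The comparison thus bears on zeros that fill whole strains, and failed estimates in single libraries stay open for the rest. Gene models that fail on a strain's sequence stay open, since 6 ribosomal protein genes were listed at 0 in all libraries. Strain differences in expression were not tested apart from this and also stay open.

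Other splits of the libraries give the counts that chance groupings reach. For each pair of strains 1 of the 10 splits of the 6 libraries, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. The real counts and the highest others were 2204 and 6 for A306 against A798, 1563 and 2 for XH against A798, and 1693 and 3 for A306 against XH. Over 100 splits of the 9 libraries, 1 gave as many genes higher in both strains (784, highest other 381). For genes lower in both, 2 gave as many (142, highest other 475). For list tests, 1 gave as many (13, highest other 9, from a split with mixed controls). In 97 splits the control group mixed strains, which widens the spread within groups and leaves few calls. These shares therefore cannot exclude chance. The splits with 381 and 475 genes kept the 3 libraries of A798 and of A306 together as the control, and splits with mixed controls gave at most 1 and 4 such genes. For the list tests the splits that kept A798 or A306 together gave 6 and 8.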

How the results depend on the processing

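The removal of ENSRNA features and of genes listed at 0 in a whole strain were tests chosen after the result was seen; the other alternatives were planned. Named genes, gene lists and the heavy to light chain percentage gave 6086 comparisons with an alternative. Of these 5773 stayed the same, 263 lost a call, 29 gained one and 21 reversed. A gene or list stayed the same if both fits passed in the same direction or neither passed. Direction was not compared where neither passed. Reversed results changed sign with a call in at least one fit. The 9 comparisons of the percentage stayed within the strain's SD. The strain differences in gland weight kept their direction with the first or the second weight alone.

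TMM scaling gave 757 higher and 794 lower in A306 than A798, 654 and 637 in XH, and 303 and 321 in both. Median centring gave 759 and 834, 559 and 709, and 271 and 335, and quantile normalization 796 and 693, 649 and 595, and 318 and 271. These scalings centre the libraries by construction. With equal FPKM sums outside the 20 most abundant genes 504 genes were higher in both; the cause was not tested.

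A 2-fold minimum, which drops small changes by construction, left 425 higher and 241 lower in A306 than A798, 283 and 156 in XH than A798, 324 and 353 in A306 than XH, and 96 and 61 in both. An adjusted p below 0.01 left 719 and 234 in XH, 685 higher in A306 than XH, and 451 and 88 in both. With FPKM of at least 5 in 3 libraries, and so fewer genes tested, 282 were lower in A306 than A798, 406 in A306 than XH and 87 in both, and 6 list tests passed. Without a filter 23 list tests passed, and with an estimated correlation 3. Lists gained without a filter include ribosomal proteins, as higher, in A306 and XH against A798, aminoacyl-tRNA synthetases and transport to the Golgi in A306, and translation factors and cell cycle in XH. Ribosomal proteins in A306 against XH passed as lower under TMM scaling, with equal sums outside the 20 most abundant genes and without ENSRNA features.

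Reversed under TMM scaling and median centring in A306 against A798 were the median of ribosomal proteins (-0.21 and -0.16), FIBL (-0.14 and -0.0854), P25 (-0.12 and -0.0671), SERPIN-4 (-0.20 and -0.16), SGF1 (-0.34 and -0.30) and FRSB (-0.10 and -0.0558). Quantile normalization reversed SERPIN-4 (-0.16), SGF1 (-0.31) and FRSB (-0.0492). As deposited, SGF1 (log2 change 0.03, limma adjusted p = 0.778) and the ribosomal list (camera adjusted p = 0.559) were not called in A306 against A798. Equal sums outside the 20 most abundant genes and the removal of ENSRNA features reversed SERPIN-4 (-0.0194 and -0.0161). In XH against A798, TMM scaling and median centring reversed ecdysone oxidase BGIBMGA000158 (-0.13 and -0.14) and ATP synthase alpha BGIBMGA001853 (-0.000617 and -0.0165). In the new direction the ribosomal list, FIBL, SGF1 and ecdysone oxidase passed the threshold under both TMM scaling and median centring, SGF1 under quantile normalization too, and P25 and SERPIN-4 under TMM scaling; the other reversed values did not pass. Beyond the centring of these scalings the cause was not tested.

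Leaving out 1 library at a time gave 1488 to 1720 higher and 400 to 435 lower in A306 than A798, 920 to 1142 and 301 to 360 in XH than A798, 878 to 1075 and 537 to 623 in A306 than XH, 631 to 706 and 111 to 136 in both, and 12 to 14 list tests. Any pairing of libraries by equal replicate numbers was weak. Residual correlations of the 9 same-number pairs ran from 0.000389 to 0.0626, none over the 0.1 set for a pair. They were all positive, and 6 of the 9 were above those with the other numbers. Pairs of unequal number ran from -0.0927 to 0.0363. With a replicate block the counts were 1666 and 414, 1042 and 346, and 993 and 596, and 8 calls of named genes were lost. Of the list calls that of haemocytes in A306 against XH was lost (camera adjusted p = 0.0631, from 0.0285 to 0.255 over its 23 alternatives). The depth is unknown, so no limit from it can be given.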
